A study of Mus musculus with 12 samples.

How the data were processed

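CTCF ChIP-seq was carried out on snap-frozen whole livers, with libraries made by the MicroPLEX v2 protocol, per the labels' protocols. The analysis used 6 peak lists, 1 for each of 3 ad libitum fed and 3 starved ChIP libraries. Groups and replicate numbers were taken from the sample titles. The input libraries (3 fed, 3 starved) were not analysed here.

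Each list held a chromosome, start, end, name and score per peak and had been deposited per library, not pooled. The score looks like a −log10 p-value or q-value of the authors' peak caller, but what it is, is not given in the sources used here. The lowest score was between 2.00 and 2.10 in every list. Per the submitters' processing notes the genome build was mm10, and FastQC, BWA 0.7.5a, SAMtools, bedtools 2.17, MACS2 and HOMER were used, with no role or order given. Whether the inputs served as control, how duplicates and blacklisted regions were treated, and the read depth are not given in the sources used here. The number of peaks a caller reports depends on depth and on the quality of the enrichment, and this cannot be separated from the state of the liver in peak lists alone.

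Peaks of the 6 lists were merged into sites when they overlapped by at least 1 bp, and a library held a site when any of its peaks formed part of it. A fed site is a site called in all 3 fed libraries, a fed-only site is called in all 3 fed and no starved library, and a starved-only site the reverse. Peaks were ranked by score within their own list as percentiles. Scores were otherwise used only to describe or filter peaks. The stricter score limit named below put 1 value on all 6 lists and so compares scores across lists. For lists of equal length, the 23926 best-scored peaks of each list were kept, the length of the shortest list. Coordinates are given in mm10, counted from 1.

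Gene positions came from RefSeq genes of assembly GRCm38.p6, the same build as mm10, with 49993 genes that had a position. This table gives no strand, exons or transcripts. The tests had been planned around the start of each gene, so both annotated ends of a gene were used in its place, and midpoints stood in for peak summits. The planned share of peaks with a CTCF motif was not analysed here because no genome sequence was used. Of the 424 genes in the lists, 423 matched the annotation by symbol.

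The number of peaks, the share of peaks near gene ends and the Jaccard index were compared by exact permutation of the group labels over all 20 labellings (10 splits). The first 2 tests were two-sided and the last one-sided, and 0.1 is the smallest p they allow. Shares have exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. For each of 22 gene lists, genes with a fed site within 5 kb of a gene end and no starved peak at any such site were compared with the other protein-coding or listed genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over lists and a threshold of 0.05. Genes and sites are not replicates. An exact test stratified by fed rank, in 20 strata of genes or 50 strata of sites, gave the values matched on fed rank.

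The lists, the main tests and the rule for named genes were fixed before the data were examined; the test stratified by fed rank was added afterwards. The lists covered gluconeogenesis, fatty acid oxidation and ketogenesis, fatty acid synthesis, sterol synthesis, bile acid metabolism, insulin and nutrient signalling, autophagy, amino acid and urea metabolism, circadian clock, CTCF and cohesin, imprinted genes, Hox clusters, clustered protocadherins, hepatocyte identity, acute phase and inflammation, endoplasmic reticulum and amino acid stress, housekeeping, and markers of Kupffer cells and macrophages, endothelial cells, stellate cells and fibroblasts, cholangiocytes and lymphocytes. Named were list genes with a fed-only or starved-only site within 5 kb, at most 6 per list by mean score rank; the 10 best-ranked fed-only and starved-only sites; the 5 best-ranked sites of listed genes called in all 6 libraries; and Ctcf, H19, Igf2, Myc, Pck1, Cpt1a, Fasn, Srebf1, Alb, Per1, Per2 and Nr1d1. Some genes that the rule names are not reported here. The rule for the 10 best-ranked sites was also applied to lists of equal length.

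Alternatives were a stricter score limit (the median of 30.4 over all lists), peaks trimmed to 200 bp or merged within 500 bp, autosomes alone, at least 2 of 3 libraries, list lengths of 11963, windows of 1, 5 and 20 kb, equal list length, a replicate block and leaving out each library. Tests on simulated data counted 200 of 200 fed-only and 200 of 200 starved-only sites put into 44909 sites. Over 12500 genes, 3.0% of 1000 random lists of 20 genes were called by Fisher's exact test at an unadjusted p under 0.05. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.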

Results

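CTCF, the zinc finger protein that binds insulators and chromatin loop anchors, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole livers of male C57BL6/Ncrl mice. The mice had either free access to normal chow, with livers taken at ZT16 (zeitgeber time, in hours after lights on), or had been starved for 24 h, with livers taken at ZT13. Each state had 3 ChIP libraries, and each library had its own list of called peaks. The 3 fed and 3 starved input libraries were not analysed here. The fed lists held 56103, 49030 and 74950 peaks and the starved lists 30752, 23926 and 29866 peaks. The number of sequencing reads behind each list is unknown, and starvation differed from the fed state in collection time as well as in feeding. The labels do not say that the libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

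The first question was whether 24 h of starvation changed the extent of the CTCF map of the liver. Fed livers gave 60028 ± 13398 peaks and starved livers 28181 ± 3712 (SD, n = 3 each), a fed to starved ratio of 2.13 and a log2 ratio of −1.09 for starved over fed. Every starved list was shorter than every fed list. The peaks covered 27.8 ± 6.94 Mb of the genome in fed and 9.26 ± 2.87 Mb in starved livers, and the mean peak width was 462 ± 15.8 bp and 324 ± 64.1 bp (SD, n = 3 each). For the number of peaks the two-sided exact permutation test over 20 labellings gave p = 0.1, the smallest value that 3 libraries against 3 allow, and covered length and mean width also gave p = 0.1 in this exact test. A permutation p under 0.05 is out of reach in this design.

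**Figure D1:**
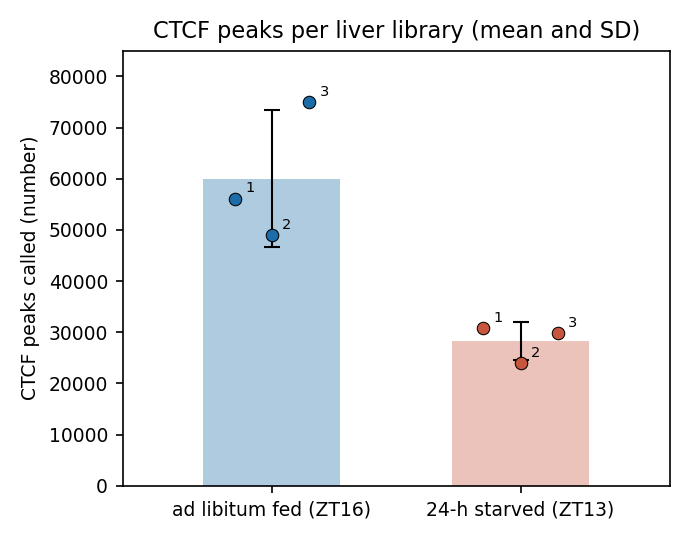
Number of CTCF peaks called in each liver library (y axis) of ad libitum fed and 24-h starved mice (x axis). Points are single libraries with their replicate number, bars are group means and whiskers are the SD (n = 3 each); the fed lists hold 49030 to 74950 peaks and the starved lists 23926 to 30752.

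The sites found after starvation lay almost entirely within the fed map. Peaks of all 6 lists that overlapped by at least 1 bp were merged into 76061 sites, of which 44909 were called in all 3 fed libraries. Of these fed sites, 31837 (70.9%, exact 95% interval 70.5 to 71.3) had a peak in at least 1 starved library, 22131 (49.3%) had a peak in all 3, and 13072 (29.1%) had a peak in none. No site was called in all 3 starved libraries and in no fed library. Of the 22134 sites called in all 3 starved libraries, 22131 (99.99%) were called in all 3 fed libraries. Each starved library held 60.04 ± 7.31% (SD, n = 3) of the fed sites, from 51.6% in starved 2 to 64.9% in starved 1. Without fed 2, the shortest fed list, the number of fed sites with no starved peak was 21003. The intervals cover counting error only, and sites are not replicates.

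Of 12 genes reported whatever their values, 8 had their best-ranked site within 5 kb called in all 6 libraries. Ctcf itself had a site over its annotated end (chromosome 8, 105636391 to 105637927) at a mean score rank of 91.1 (percentile) within the fed lists and 79.1 within the starved lists, and another beyond its other end (105685672 to 105686311) at 82.2 and 80.1. Srebf1, the transcription factor of lipogenesis, had a site inside the gene (chromosome 11, 60199354 to 60200412) at ranks 99.4 and 97.5. Pck1, the cytosolic enzyme that commits oxaloacetate to gluconeogenesis, had a site over its annotated end (chromosome 2, 173158834 to 173159916) at 89.3 and 91.4. Cpt1a, which loads long-chain fatty acids for import into mitochondria, had its best site outside the gene (chromosome 19, 3388706 to 3389715) at 92.5 and 58.8. Myc had its best site outside the gene (chromosome 15, 61983034 to 61983703) at 95.4 and 85.7. At the H19 gene, a noncoding RNA of the imprinted Igf2 region, the site between 142580013 and 142581244 on chromosome 7 was called in all 6 libraries, at ranks 67.7 and 37.3. Scores are the authors' own peak values, and ranks from lists of different lengths do not measure a change.

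The best sites of Fasn, Nr1d1 and Alb were called in fewer starved libraries. Fasn, the fatty acid synthase, had 3 sites within 5 kb of its ends, and the best of them (chromosome 11, 120823614 to 120824618, fed rank 64.0) was called in all 3 fed and 1 starved library. Nr1d1, a repressor of the circadian clock, had 2 sites, of which the better (chromosome 11, 98762662 to 98763062, fed rank 59.7) was called in 3 fed and 2 starved libraries. Alb, the albumin gene, had 1 site, called in 1 fed library. Igf2 had 0 sites within 5 kb of its ends. Of the clock genes Per1 and Per2, Per1 had a site in all 6 libraries (chromosome 11, 69092118 to 69093306, ranks 96.3 and 95.6) and 1 site in all 3 fed and no starved library (69099728 to 69100132, fed rank 32.0). Per2 had a site over its end in all 6 libraries (chromosome 1, 91458524 to 91460178, ranks 58.9 and 31.8) and 2 sites in the fed libraries alone, at 91412778 and 91460481.

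The 5 best-ranked sites of the listed genes that were called in all 6 libraries lay at Esco1, a cohesin acetyltransferase (chromosome 18, 10609221 to 10610864, fed rank 99.6), Dgat2, which makes triglycerides (chromosome 7, 99150704 to 99152438, 99.4), Srebf1, Col1a1, a collagen gene of fibroblasts (chromosome 11, 94936171 to 94937899, 98.7), and Crtc2, a CREB coactivator of gluconeogenesis (chromosome 3, 90264665 to 90265612, 97.9). Crtc2 also had a site inside the gene (90254526 to 90254864, fed rank 33.0) that was called in all 3 fed and no starved library.

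Whether a fed site was found after starvation followed its rank in the fed lists. Of the sites with a mean fed rank between 20 and 30, 12.3% were called in at least 1 starved library, against 46.8% between 40 and 50, 81.9% between 50 and 60 and 98.6% between 60 and 70. None of the 17418 sites above a rank of 70 was without a starved peak, and 17266 of them (99.1%) were called in all 3 starved libraries. The limit of 70 was chosen after the data were seen. It lies just above the highest fed rank of a site with no starved peak (69.86), so the count of 0 is no test by itself. Leaving out 1 library at a time gave 0 to 3 sites above 70 without a starved peak, the 3 without starved 1. The median fed rank was 33.4 for sites with no starved peak and 72.7 for the others. The 10 fed sites with no starved peak that ranked best genome-wide had ranks between 65.1 and 69.9. They lay inside Vps41, a subunit of a vesicle tethering complex (chromosome 13, 18757988 to 18758398), inside Prkag1, a regulatory subunit of the energy sensor AMPK (chromosome 15, 98821344 to 98821804), and at the end of Ylpm1 (chromosome 12, 84995750 to 84996866). The others were nearest to Gm15521, Prtg, Gm39116, Neurl1b, Gm36503, Gm27521 and Ces2h, a carboxylesterase gene.

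**Figure D2:**
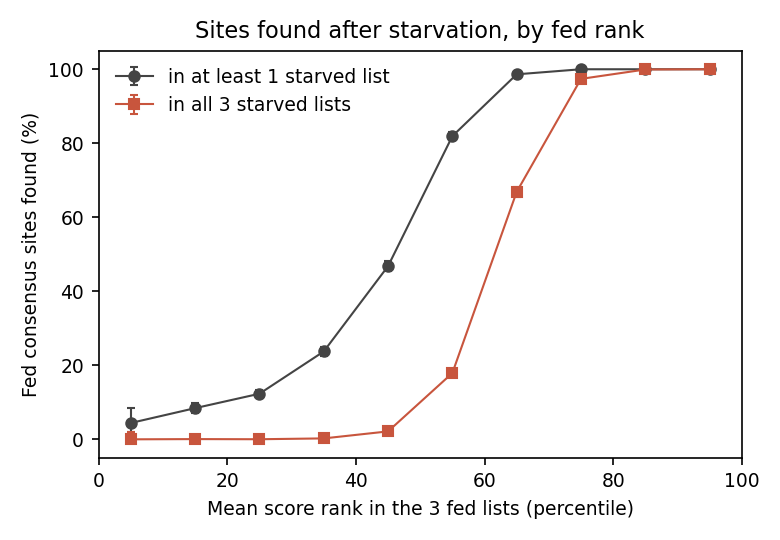
Share of the sites called in all 3 fed libraries that were also called after starvation (y axis, %) by their mean score rank in the fed lists (x axis, percentile, in bins of 10). Grey circles are sites in at least 1 starved list and red squares sites in all 3; whiskers are exact 95% intervals. Shares rise from 4.42% and 0% in the lowest bin to 100% in the highest.

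Most fed CTCF sites near genes of fasting metabolism were called in at least 1 starved library, and fewer were called in all 3. Across the genome, 12500 protein-coding or listed genes had a fed site within 5 kb of an annotated gene end, and 2004 of them (16.03%) had no starved peak at any of those fed sites. Counted as distinct fed sites, 13 of 17 in gluconeogenesis, 20 of 24 in fatty acid oxidation and ketogenesis, 27 of 34 in fatty acid synthesis, 14 of 18 in sterol synthesis and 4 of 6 in bile acid metabolism had a peak in at least 1 starved library. In all 3 starved libraries it was 7 of 17, 11 of 24, 13 of 34, 6 of 18 and 2 of 6. Over all fed sites the shares were 70.9% in at least 1 and 49.3% in all 3, and the lists were not tested against them by site. Counted as genes with no starved peak, in gluconeogenesis this held for 1 of 10 genes, in fatty acid oxidation and ketogenesis for 2 of 13, in fatty acid synthesis for 0 of 15, in sterol synthesis for 2 of 14, in bile acid metabolism for 2 of 5, in insulin and nutrient signalling for 3 of 22, in autophagy for 1 of 14 and in amino acid and urea metabolism for 1 of 13. None of the 22 lists differed from the other genes by Fisher's exact test with Benjamini-Hochberg adjustment (lowest adjusted p = 0.664), and 1 did at an unadjusted p under 0.05. Matched on fed rank, an exact stratified test also called 0 lists (lowest adjusted p = 0.466). For fatty acid synthesis, 0.54 genes were expected at matched fed rank where 0 were seen. In simulations, lists of 20 genes with odds of 4 put in were called by the unmatched Fisher's exact test, without adjustment, in 82.9% of draws. The real lists held 2 to 38 genes with a fed site, those from gluconeogenesis to bile acid metabolism 5 to 15, and were judged after adjustment. The power of the test as used was not measured, so a loss of that size could have been missed in these lists.

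Single sites of these lists were nevertheless called in the fed libraries alone. Ppara, the nuclear receptor that drives fatty acid oxidation, had such a site inside the gene (chromosome 15, 85735407 to 85735798, fed rank 52.3). Hadha and Hadhb, the subunits of the mitochondrial trifunctional protein, shared 1 between them (chromosome 5, 30155327 to 30156017, 36.7). Acadvl, the very long-chain acyl-CoA dehydrogenase, had 1 outside the gene (chromosome 11, 70005507 to 70005988, 48.5). In fatty acid synthesis, Acaca, an acetyl-CoA carboxylase (chromosome 11, 84134210 to 84134742, 51.0), and Elovl6, a fatty acid elongase (chromosome 3, 129529300 to 129529693, 49.5), each had 1. Abcb11, the bile salt export pump, had 1 just outside its end (chromosome 2, 69342964 to 69343350, 51.7), and Arg1, the last enzyme of the urea cycle, 1 outside (chromosome 10, 24911762 to 24912034, 14.6). The list of insulin and nutrient signalling had 16 distinct fed-only sites among 46 fed sites, including those near Rptor, Tsc1 and Irs1, at fed ranks of 39.2, 39.2 and 32.7. In autophagy, 6 of 28 fed sites were fed-only, among them those at Becn1 (39.4) and Ulk2 (34.3). Of the 98 named sites that were fed-only at all peaks, 87 had no peak in any list of equal length and 9 were still called in all 3 fed lists there; at the stricter score limit it was 53 and 12.

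Of the 16 genes of the hepatocyte identity list with a fed site, 0 had no starved peak at those sites. At matched fed rank, 0.04 such genes were expected. Of the 29 distinct fed sites of this list, 26 were called in at least 1 starved library. Apoa1, an apolipoprotein gene, had both a site in all 6 libraries and a fed-only site (chromosome 9, 46228640 to 46229086). Among genes with a fed site, the circadian clock had 1 gene of 16 with no starved peak, acute phase and inflammation 3 of 11, endoplasmic reticulum and amino acid stress 3 of 13, housekeeping genes 3 of 13, and CTCF and cohesin genes 3 of 14. Nipbl, the cohesin loader, had 1 site within 5 kb of its ends, which was fed-only (chromosome 15, 8291221 to 8291602, fed rank 51.0), as was the 1 site at Smc1a, a cohesin subunit (chromosome X, 152015567 to 152016183, 35.8). Of the imprinted genes with a fed site, 4 of 20 had no starved peak there; Magel2 had both a site in all 6 libraries and a fed-only site (chromosome 7, 62375623 to 62376085, 55.8). In the Hox clusters it was 1 of 29 genes, with 1.25 expected at matched fed rank. Of their 25 distinct fed sites, 17 were called in all 3 starved libraries. Marker genes of other liver cells were few: 0 of 2 for Kupffer cells and macrophages, 2 of 4 for endothelial cells, 0 of 6 for stellate cells and fibroblasts, 1 of 5 for cholangiocytes and 0 of 2 for lymphocytes. None of these counts passed the adjusted Fisher's exact test given above.

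**Figure D3:**
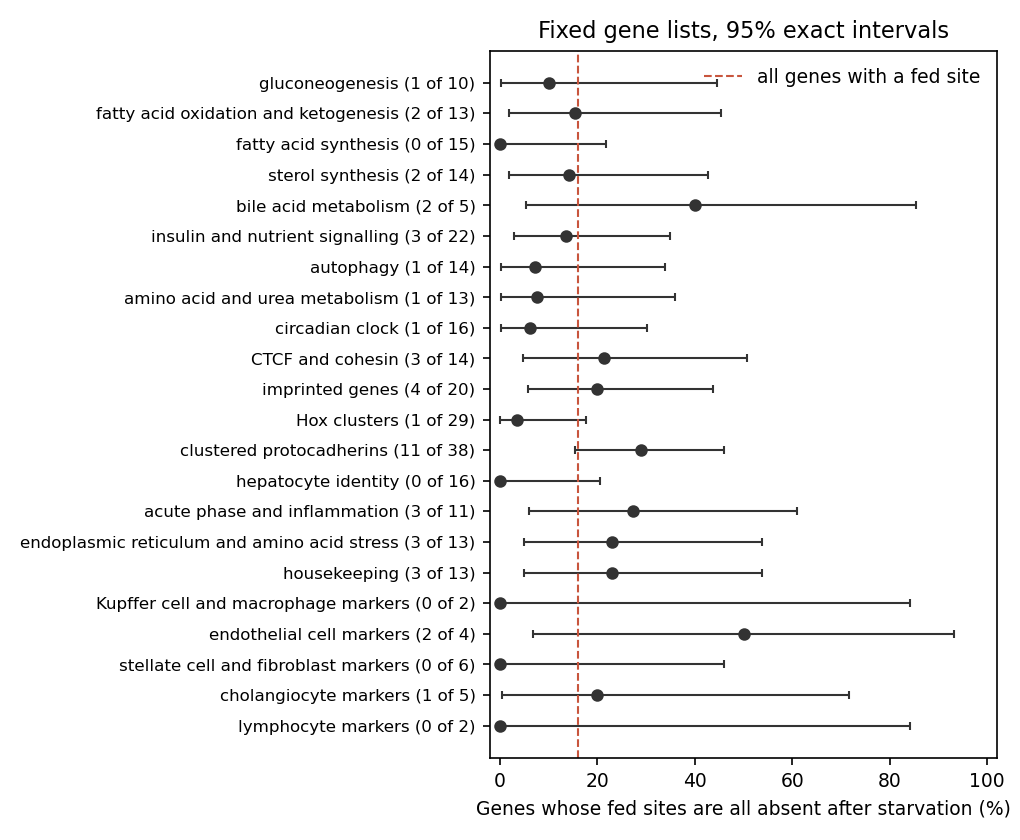
Share of the genes with a fed CTCF site within 5 kb of a gene end whose fed sites all had no starved peak (x axis, %) for each of the 22 gene lists (y axis, with the number of such genes and of genes with a fed site). Points are shares, whiskers exact 95% intervals, and the dashed line marks 16.03% for all 12500 genes; no list passed the adjusted test.

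The share of genes with a peak within 5 kb was lower in every starved library, at 37.2 to 46.4% of 21903 genes against 58.9 to 68.8% in the fed libraries. Relative to that share in the same library, 9 of the 22 lists reached the smallest exact permutation p of 0.1, where chance gives 2.2, and none passed after adjustment (lowest adjusted p = 0.244, exact permutation test). The relative share was higher after starvation for fatty acid synthesis (log2 0.28), amino acid and urea metabolism (0.41), Hox clusters (0.47), hepatocyte identity (0.31), stellate cell and fibroblast markers (0.32) and lymphocyte markers (0.57). For the lymphocyte markers the share of genes with a peak was 22.2% in all 6 libraries, so that value reflects the share over all genes alone. It was lower for clustered protocadherins (−0.32), acute phase and inflammation (−0.45) and endothelial cell markers (−0.90). With lists of equal length, fatty acid synthesis (−0.17), hepatocyte identity (−0.16) and stellate cell and fibroblast markers (−0.20) had the opposite sign, and the other 6 lists lay between −0.02 and 0.04.

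The 1 list with an unadjusted p under 0.05 was that of the clustered protocadherins, cell surface proteins whose promoter choice depends on CTCF. Here 11 of 38 genes (28.9%) had no starved peak at their fed sites, against 15.99% of other genes, with an unadjusted p of 0.0428 and an adjusted p of 0.664 by Fisher's exact test. Neighbouring protocadherin genes share sites. Counted as distinct sites across the cluster (chromosome 18, 36930285 to 37841873), 11 of 27 fed sites (40.7%, exact 95% interval 22.4 to 61.2) had no starved peak. Elsewhere it was 29.1% (Fisher's exact p = 0.204), and 6 of the 27 were called in all 3 starved libraries. At matched fed rank, 9.97 of the 27 were expected without a starved peak (stratified exact p = 0.759). Their median fed rank was 52.7, against 61.0 over all fed sites. Counted as genes, 6.78 were expected at matched fed rank (stratified exact p = 0.0212, adjusted p = 0.466). Fed-only sites included those near Pcdhb13 and Pcdhb14 (37447442 to 37447741), Pcdha9 (36997632 to 36997920), Pcdhb5 (37320084 to 37320476) and Pcdha4 (36953096 to 36953515). With a window of 20 kb, 17 of 49 protocadherin genes had no starved peak and the adjusted Fisher's exact p was 9.20e-07, a count in which 1 site enters for several genes.

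**Figure D4:**
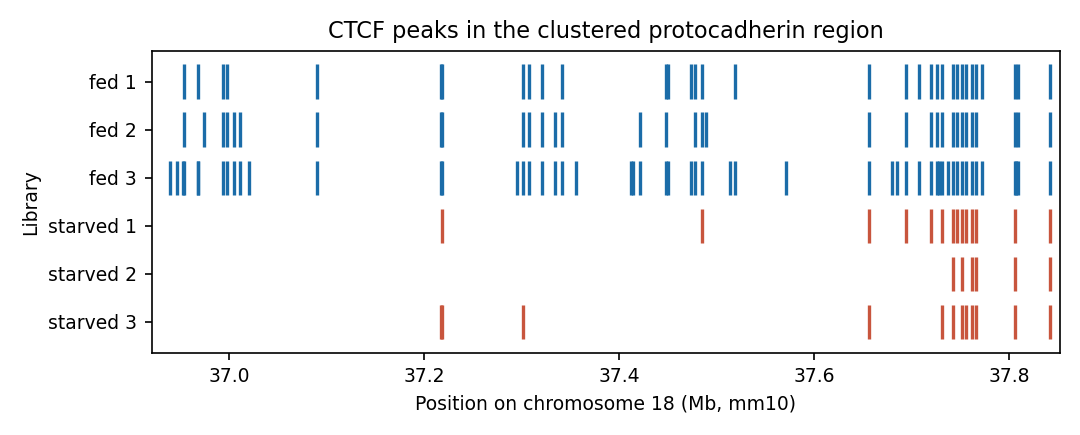
Map of the CTCF sites (vertical lines) in the clustered protocadherin region of chromosome 18 (x axis, position in Mb, mm10) in each of the 6 libraries (y axis). Of the 27 sites called in all 3 fed libraries, 6 were called in all 3 starved libraries and 11 in none.

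Where peaks lay relative to genes was compared next. Of the fed peaks, 22.8 ± 0.81% had their midpoint within 1 kb of an annotated gene end, against 20.9 ± 1.67% of the starved peaks (SD, n = 3 each), a difference of −1.91 percentage points with a two-sided exact permutation p of 0.2. The same peaks moved by 100 kb gave 9.65 ± 0.08% and 9.95 ± 0.01%. The sign of the difference turned with lists of equal length (0.69 points) and at a stricter score limit (1.33 points), so no direction held across these settings. Peaks inside genes made up 64.5 ± 1.42% of the fed and 59.7 ± 1.62% of the starved lists (exact permutation p = 0.1), and 58.2 ± 0.40% and 58.3 ± 0.47% with lists of equal length. By chromosome, the share of fed sites with no starved peak ran from 26.4% on chromosome 10 to 32.7% on chromosome X, leaving out chromosome Y with 19 sites, and no chromosome passed an adjusted Fisher's exact test (lowest adjusted p = 0.0647).

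To compare the groups without the difference in list length, the 23926 best-scored peaks of each list were used. The maps of fed and starved livers were then close: 98.8% of the 21707 sites in all 3 fed lists were found in at least 1 starved list and 88.9% in all 3. There were 261 fed-only sites, led by those nearest to Wfdc10 (chromosome 2, 164655503 to 164656358), Eif4e2, which encodes a cap-binding protein (chromosome 1, 87217824 to 87218704), and Gm28876. There were 103 starved-only sites, led by those nearest to Gm51937 (chromosome 11, 11844139 to 11844622), Leprot (chromosome 4, 101682926 to 101683268), Raph1 (chromosome 1, 60565206 to 60565812) and Cyp2c70, a bile acid hydroxylase of rodents (chromosome 19, 40168353 to 40168702). Each of the 103 overlapped a peak of a full fed list, and 226 of the 261 overlapped a peak of a full starved list. Without starved 2, and so with lists of 29866 peaks, these counts were 855 and 489, and leaving out any other library gave 389 to 478 and 167 to 247; fewer libraries raise such counts by construction.

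Over all peaks, libraries shared more sites within groups than between them on average, while at equal list length this held for the fed libraries alone. The mean Jaccard index, the number of shared sites over the number of sites in either library, was 0.740 within groups (0.629 to 0.811, 6 pairs) and 0.476 between groups (0.313 to 0.610, 9 pairs). The difference of 0.264 was the largest of the 10 splits (one-sided exact permutation p = 0.1, the smallest possible). List length limits the index between groups, because at least 99.8% of the sites of each starved library were also called in a fed library. The lowest value, 0.313, was that of fed 3 with 74162 sites and starved 2 with 23201. The difference over all peaks is thus not separate from that in peak number. With lists of equal length the mean index was 0.860 within and 0.840 between, a difference of 0.020 with the same exact permutation p of 0.1. The fed pairs then ran from 0.885 to 0.897, the starved pairs from 0.812 to 0.842 and the pairs between groups from 0.817 to 0.858.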

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

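Chosen only after the data were seen were the tests on protein-coding genes alone, matched on fed rank, on gene lists without single libraries, on distinct protocadherin sites, on fed ranks above 70 without single libraries, and on relative shares and single sites at equal list length. With a stricter score limit or autosomes alone, the lower peak number after starvation, the Jaccard difference and the absence of starved-only sites kept their direction. Merging within 500 bp kept the last 2. The log2 ratios of peak number ran from −1.22 to −0.90 when single libraries were left out. The stricter limit was 1 score for all 6 lists and left 27004 to 35335 fed and 10227 to 15371 starved peaks. It therefore does not remove a difference in depth or enrichment. Over all peaks the Jaccard difference is not separate from the difference in list length. With at least 2 of 3 libraries of a group and none of the other, there were 23023 fed-only and 2 starved-only sites. Trimming peaks to 200 bp gave 288 starved-only sites, each overlapped by an untrimmed fed peak, so they follow from the trimming. Leaving out single libraries gave 13329 to 21003 fed-only sites, 0 to 2 starved-only sites and 60.5 to 70.4% of fed sites kept; 21003 and 60.5% came without fed 2, and fewer libraries raise such counts by construction. At equal list length it gave 389 to 855 fed-only and 167 to 489 starved-only sites, and a list length of 11963 gave 151 fed-only and 128 starved-only sites. The gene-end share turned to 1.33 points at the stricter score limit and 0.69 at equal length; the cause was not tested. The window of 20 kb gave 1 gene list past the threshold, the protocadherins, whose neighbouring genes share sites. At equal length the relative share of fatty acid synthesis (−0.17), Hox clusters (−0.0014), hepatocyte identity (−0.16), stellate cells and fibroblasts (−0.20) and lymphocytes (−0.0014) had the opposite sign, where −0.0014 is about no change, and the smallest exact p was reached by 4 lists in place of 9: sterol synthesis, autophagy and cholangiocytes, which were not among the 9, and hepatocyte identity with its sign turned. Of 146 named sites, 116 moved, 27 were the same and 3 turned at equal length, where fed minus starved libraries was −1, among them those near Srebf1 (from 60222853 and 60224667); 121 moved at the stricter score limit, 6 with merging within 500 bp and none with trimming to 200 bp. With the replicate block, the paired log2 ratio of peak number was −1.08 ± 0.23 (SD, n = 3, exact sign-flip p = 0.25, the smallest possible). The gene-end difference was −1.91 (exact sign-flip p = 0.5). A correlation across sites, not that of raw presence, was 0.04, −0.15 and −0.09 for same-numbered libraries. Of the fed libraries, fed 1 alone correlated best with its own number. Low values here do not mean unrelated presence: at least 99.8% of the sites of each starved library were also called in a fed library. These correlations were not tested, and whether the numbers pair the libraries is unknown. The share of peaks with a CTCF motif, and the other settings chosen for it, were not run. Read depth is unknown, so how much of the difference in peak number it limits cannot be measured here.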

Other observations

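Chosen only after the result was seen were the tests of fed rank for the fed-only sites, of other splits of the libraries, of single starved libraries, of list length in the starved group, and the split by protocadherin family; the tests of full lists, of list length in the fed group, of peak width and of neighbouring sites were written first. Of the fed sites between the ends of the Pcdhg genes (chromosome 18, 37661775 to 37841873), 11 of 13 were called in at least 1 starved library and 6 in all 3, against 2 of 7 in the Pcdhb part and 0 of 4 in the Pcdha part. The median fed ranks were 62.4, 39.6 and 31.5, and sites of the same fed ranks genome-wide gave 2.64, 3.76 and 3.24 sites with no starved peak where 2, 5 and 4 were seen; the other 3 fed sites lay between the families.

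A total of 76 sites were called in starved libraries and in no fed library, 74 of them in a single library. The 2 called in a pair of libraries (starved 2 and starved 3) lay on chromosome 8, with midpoints 179 bp from an end of Gsr, the gene of glutathione reductase (33698219 to 33698464), and 22490 bp from Rbpms (33805032 to 33805236); both were chosen after their values were seen. At equal list length, 31.1% of the 103 starved-only sites (exact 95% interval 22.3 to 40.9) lay within 1 kb of a gene end, against 15.3% of the 261 fed-only sites (11.2 to 20.3, Fisher's exact p = 0.00119). Of 23116 pairs of neighbouring fed sites within 20 kb, 13960 (60.4%) were both called or both not called after starvation. The mean was 59.9% in 1000 reassignments at matched fed rank (13673 to 14022 pairs, one-sided permutation p = 0.021). The count lay within the range of the reassignments, the outcome written beforehand for no clustering, so the prediction of clustering was not met. That bound was too wide to exclude clustering at this p, so clustering of absence along the chromosome stays open.

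The first pattern weighed is that starvation came with 13072 fed-only and 0 starved-only sites. Loss at selected sites whatever their fed rank is argued against by the median fed ranks. These were 33.4 for fed sites with no starved peak and 72.7 for the others. Above a fed rank of 70, 0% of sites had no starved peak, against 29.1% over all fed sites. That limit was chosen after the data were seen and adds no separate test. A starved list that detects fewer peaks, the weakest first, would give this order by rank. Less CTCF on chromatin everywhere after starvation predicts the same order, and the kept site had the higher fed rank in 95.01% of pairs of a kept and an absent site, so this and lower detection cannot be told apart without read depth, and the collection time differed as well. The 10 splits of the libraries are too few for a share under 0.05: the real split alone had as many as 13072 fed-only sites (1 of 10; highest other 260).

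The second pattern is that there were 261 fed-only sites at equal list length. Of these, 86.6% had a peak in at least 1 full starved list. The shortest starved list was kept whole, so such peaks can only have fallen below the rank limits of the longer starved lists. To count as fed-only, a site had to pass fed rank limits of 51.2 to 68.1. Between mean fed ranks of 60 and 70, 98.6% of fed sites had a peak in at least 1 starved list. A high share was thus likely whatever the cause, so the 86.6% does not tell a rank limit from a change. A change at any of the 261 sites stays open, untested. The 10 splits are again too few for a share under 0.05, with 261 fed-only and 103 starved-only sites in the real split (1 of 10 each) and at most 84 in any other.

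The third pattern is that, at matched fed rank, sites within 1 kb of a gene end were without a starved peak less often than expected (2719 sites against 3332, ratio 0.816), while without matching the shares differed little (28.3% against 29.3% of other sites, Fisher's exact p = 0.0625). Matched on width as well, the ratio was 0.916 (stratified exact p = 4.58e-28, over sites, which are not replicates), so part of the pattern went with width. The width was that of the merged site, starved peaks included, and was matched in coarse classes. Peak width as the cause of the rest is therefore not excluded. List length stays open: its test, written first, was met by the sites that fed 2, the shortest fed list, lacked (0.842), but those that fed 1 lacked gave 1.11 and those that starved 2, the shortest starved list, lacked gave 1.14. The pattern was present in starved 1 and starved 3 (0.836 and 0.907) but not in starved 2 (0.997), which is consistent with differences between single libraries. An effect of starvation at gene ends in some of the livers stays open and was not tested.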
